A study of Mus musculus with 15 samples.

How the data were processed

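The series holds single-nucleus RNA-seq of the mouse enteric nervous system. Per the labels' protocols, the myenteric or submucosal layer was dissected from stomach, small intestine or colon, nuclei were isolated in a buffer that differed between the layers, stained with an antibody against HuC/D and sorted, and libraries were made with 10x Chromium 3' chemistry version 3.1. Of 15 samples, 14 were used, and a sample of proximal colon from the myenteric layer was not analysed here. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, restricted to barcodes called as cells, and the authors made them with Cell Ranger 6.1 on mm10, per the submitters' processing notes. Whether intronic reads were counted, and with which strand rule, was not given in the sources used here. Sequence depth per library, as the files show it, ran from 7417008 to 83127032 UMIs, so genes under about 1 CPM rest on few UMIs in the shallow libraries. The labels give no batch and no animal for a library.

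Gene IDs numbered 32176, of which 32098 were found in GENCODE mouse release 21, whose mm10 coordinates are given 1-based, and 27 symbols were shared by more than 1 ID and kept apart by ID. Nuclei were kept with at least 500 detected genes and at most 5% mitochondrial UMIs, which left 106497 of 118221 barcodes. Scrublet (in scanpy 1.11.5) was run per library, but its automatic threshold marked under 0.5% of barcodes in 13 of the 14 libraries, which counts as a failed call. The nuclei with the highest scores, at a rate of 0.8% per 1000 barcodes, were therefore left out instead, a rule chosen after seeing the data, which removed 2.27% to 13.8% of a library and left 97207 nuclei. Counts were scaled to 10000 per nucleus and logged, 3000 variable genes and 40 principal components were taken, a Harmony-type correction with 50 clusters was applied for library, and nuclei were joined by 20 nearest neighbours and clustered by Leiden at resolution 1 (igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0). Neuronal clusters were found by neuron markers and clustered again the same way. Clusters with over 25% doublet nuclei were left as mixed.

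Neuron clusters were named excitatory or inhibitory motor-like, interneuron-like or sensory-like from fixed markers where at least 3 markers were detected at 10 CPM and the class score reached 0.5, a minimum set after seeing the data. Clusters 0, 2, 4, 7, 14 and 17 were excitatory, 1, 3 and 11 inhibitory, 5 interneuron-like and 10 sensory-like, and 7 clusters stayed unnamed. Of the named clusters, 14 and 17 took 57.0% and 97.7% of their nuclei from the library labelled colon.

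Cells were not treated as replicates. UMIs were summed over the neurons of each library, which left 47679 neurons in the sums, and tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, glmQLFit and glmQLFTest and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 with at least a 2-fold change. The 3 organs were compared in 1 fit of 11 myenteric libraries, the layers in a fit of 9 intestinal libraries with organ as a term, and the antrum with the other gastric regions in the organ fit with the stomach divided. Class-resolved fits took libraries with at least 30 nuclei of the class. Standard errors are the log2 fold change divided by the square root of its F value. Class shares were compared by exact two-sided permutation over libraries, within organ for the layers, with adjustment over 20 tests. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. CPM in the text are TMM-scaled sums over neurons unless another nucleus type is named, with SD over libraries. A layer by organ interaction was tested in the 9 intestinal libraries, and 1 gene called there is not reported here.

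Groups, tests, lists, markers and the alternatives were fixed before the data were examined, except where the text says otherwise. Genes were named by a rule fixed at the same time. In each all-neuron comparison it took the 10 called genes with the largest change in each direction, at 20 CPM or more in the higher group and with groups that did not overlap, without predicted genes, markers of other cells, sex-linked, mitochondrial or ribosomal genes. It further took up to 4 called members of each list with the smallest adjusted p, and Elavl3, Elavl4, Nos1, Vip, Chat and Tac1 whatever their result. In the classes it took 3 genes per direction. Some genes the rule named are counted in the text without their own values.

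Alternatives were DESeq2 1.42.0 with its Wald test, its size factors in edgeR, no expression filter, no fold threshold, nuclei with at least 1000 genes, doublets kept, genes with higher CPM in non-neuronal nuclei left out, libraries thinned to the smallest sum, a term for library numbers under 50 against higher ones, only the groups compared, antrum as the only gastric region, small intestine alone for the layers, at least 100 nuclei in the class fits, Leiden resolution 2, clustering without library correction, and each library left out in turn. Added after seeing the data were the automatic doublet threshold, a term for the ribosomal protein share of neuronal UMIs, and the library labelled colon left out of the shared fit. Intervals are exact (Clopper-Pearson for shares, Poisson for counts) at 95%, except that of an odds ratio, which is a normal approximation. They cover counting error only. Barcodes shared between any 2 libraries reached at most 0.63% of the smaller one.

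The fits were tested on simulated data drawn from the real means and library sizes, with 200 genes changed 2-, 4- or 8-fold. Each gene was drawn independently, without effects shared by the genes of a library. The false calls below therefore do not measure those that such effects could cause in the real data. For colon against small intestine the test recovered 0%, 34.4% and 64.6% of them at these sizes among 18033 genes, with 5 false calls. For stomach against small intestine it recovered 1.54%, 43.8% and 69.2% among 17946 genes, with 2 false calls, and for stomach against colon 1.61%, 29.2% and 66.2% among 18046 genes, with 3. For the layers it recovered 1.49%, 32.8% and 63.1% among 16694 genes, with 4 false calls, and for antrum 0%, 19.7% and 40.3% among 18775 genes, with 3. DESeq2 gave 44 to 79 false calls in the same simulations. Figures and tables used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15.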

Results

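Nuclei from the mouse enteric nervous system were enriched for neurons by sorting with an antibody against HuC/D, the protein products of Elavl3 and Elavl4, and their RNA was counted by droplet single-nucleus sequencing. The 14 libraries analysed came from the myenteric layer, which lies between the muscle coats, of the small intestine (n = 3), colon (n = 3) and stomach (n = 5). Others came from the submucosal layer of the small intestine (n = 2, each labelled whole small intestine) and colon (n = 1, labelled proximal colon). The small intestinal myenteric libraries were from ileum (replicates 1 and 3) and duodenum (replicate 2). The colonic ones were from proximal colon (replicate 1), colon with no part named (replicate 3) and mid colon (replicate 4). The gastric ones were from antrum (replicates 1, 3 and 5), corpus (replicate 2) and fundus (replicate 4). Total UMIs per library ran from 7417008 in the corpus to 83127032 in ileum replicate 1, over 118221 barcodes. After filtering, 97207 nuclei were kept, and 47679 neurons were analysed. The summed neuronal UMIs of a library lay between 4136222 in submucosal colon and 44246856 in ileum replicate 1. The median of these neurons held 1390 UMIs in proximal colon replicate 1 and 16421 in antrum replicate 5. Xist and Y-linked genes were both counted in neurons of 7 of the 14 libraries, at over 20 CPM each, and 1 of the 2 alone in the other 7. Libraries therefore differed in their mix of animals, some may pool animals, and no fit took this into account. The labels do not tie libraries to animals, so p-values measure only the spread between these libraries, which may be technical.

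Neurons made up 17.4% of the kept nuclei in antrum replicate 3 and 77.2% in the corpus. Smooth muscle nuclei made up 6.43% to 17.9% of the intestinal myenteric libraries and 1.78%, 2.10% and 7.92% of the submucosal ones. Intestinal epithelium made up 20.7%, 23.3% and 30.8% of the submucosal libraries and 0.721% to 14.3% of the myenteric ones. Transcripts of neuropeptide genes were also counted outside neurons. Throughout, non-neuronal nuclei are all kept nuclei outside neuronal and mixed clusters, so they include unnamed clusters of low UMI counts. In 1 of these Elavl4 stood at 825 and Snap25 at 876.5 CPM, so this pool holds nuclei like neurons. Its CPM is therefore not a measure of other cell types alone. Pooled over the 11 myenteric libraries, Vip, which encodes vasoactive intestinal peptide, stood at 347 CPM in non-neuronal nuclei and 212 CPM in neurons, and Tac1, which encodes substance P, at 388 and 227 CPM. In smooth muscle nuclei of the library labelled colon, Barx1, a homeobox gene, stood at 57.2 CPM (exact Poisson 95% interval 48.6 to 66.8), against 71.6 to 208 CPM in the 5 gastric libraries and 0 UMIs in the other intestinal myenteric libraries. Hox paralogues 9 to 13 stood there at 87.6 CPM (76.9 to 99.3), against 471 and 240 CPM in the other colonic myenteric libraries and at most 14.7 CPM in the gastric ones. This library, colon replicate 3, is named throughout as the library labelled colon, and counts of called genes in the comparisons of organs and layers are also given without it.

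**Figure D1:**
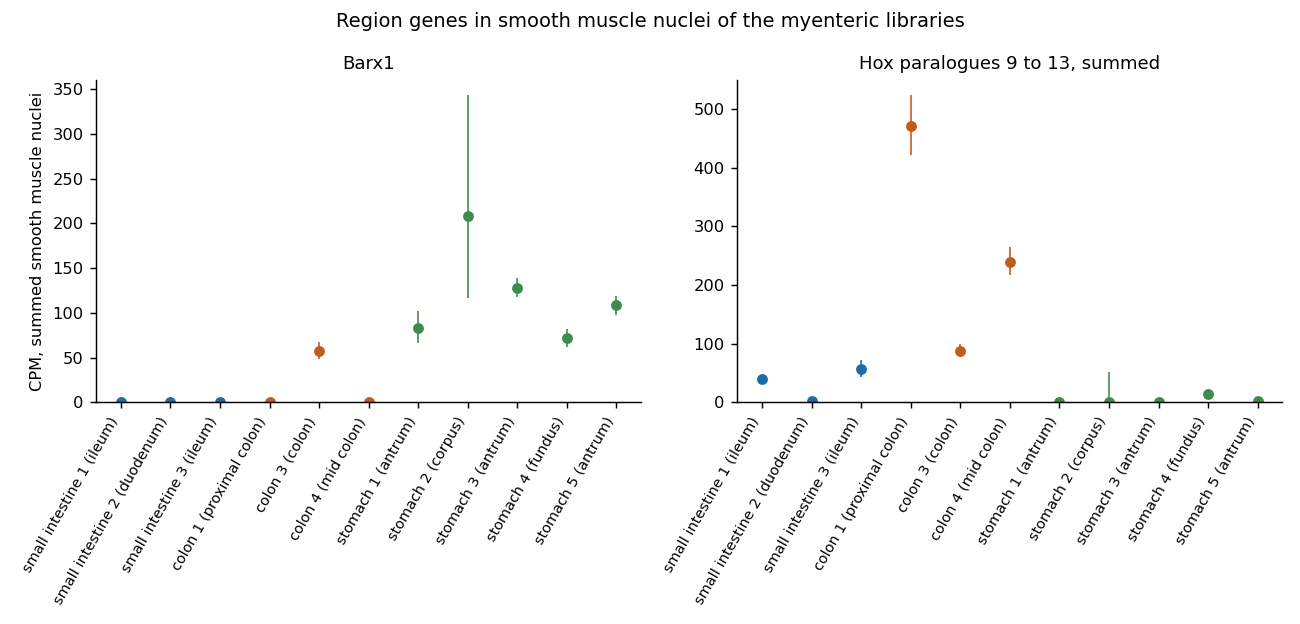
Barx1 CPM and the summed CPM of Hox paralogues 9 to 13 in smooth muscle nuclei of the 11 myenteric libraries, 1 point per library with its exact Poisson 95% interval, which covers counting error only. The library labelled colon, at 57.2 and 87.6 CPM, has UMIs of both, the other intestinal libraries have no Barx1 UMI, and the gastric libraries lie at 71.6 to 208 CPM of Barx1.

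Colon was compared with small intestine to ask how myenteric neurons differ along the intestine. Cysltr2, a receptor for cysteinyl leukotrienes, averaged 17.1 ± 0.541 CPM in colon (SD, n = 3) and 94.3 ± 11.98 CPM in small intestine (n = 3), a log2 fold change of -2.46 (SE 0.19, adjusted p = 0.00114 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ano2, a calcium-activated chloride channel, averaged 32.6 ± 7.41 against 229 ± 86.9 CPM (log2 fold change -2.81, SE 0.33, adjusted p = 0.0213). The T-box transcription factor gene Tbx2 averaged 19.3 ± 3.39 against 63.9 ± 13.3 CPM (-1.73, SE 0.21, adjusted p = 0.0213). Higher in colon were Ahr, the aryl hydrocarbon receptor, at 70.9 ± 21.1 against 14.7 ± 2.97 CPM (2.27, SE 0.29, adjusted p = 0.0217), and Thsd7a at 312 ± 144 against 69.5 ± 8.95 CPM (2.17, SE 0.32). Rasgef1b (-2.90, SE 0.36) and Efr3a (-1.26, SE 0.18) were lower, as were Dapk2 (-3.17), Iqgap2 (-2.66), Adamts6 (-2.53), Nectin3 (-1.73) and Adgrl2 (-1.20). Pooled CPM of these last 5 genes was higher in non-neuronal nuclei than in neurons of the same libraries, for example 139 against 23.8 for Iqgap2. In all, 16 of 18413 genes were called at an adjusted p under 0.05 with at least a 2-fold change, 4 higher and 12 lower in colon. Ano2 and Cysltr2 also lead the sensory-like neuron cluster, whose share of neurons was 2.55% in colon and 9.80% in small intestine, so their level and that share are not independent. The fitted folds of 7.02 and 5.50 compare with a ratio of 3.85 for the share, and no test set them against each other. In clustering without library correction Dapk2, Iqgap2 and Rasgef1b were also among the leading genes of sensory-like clusters, so their levels may depend on that share too. Not called were Elavl4 (0.04, SE 0.23), Elavl3 (-0.26, SE 0.45), Nos1 (0.80, SE 0.42), Vip (0.35, SE 0.69), Chat (-0.31, SE 0.26) and Tac1 (1.17, SE 0.92), each with an adjusted p of 1. On mm10, Cysltr2 (ENSMUSG00000033470) lies on chromosome 14 from 73025603 to 73049114. Ano2 (ENSMUSG00000038115) lies on chromosome 6 from 125690419 to 126040126, and Ahr (ENSMUSG00000019256) on chromosome 12 from 35497974 to 35535038.

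The count of called genes in colon against small intestine fell with each of the 6 libraries left out. It was 8 without small intestine replicate 1, 1 without replicate 2 and 1 without replicate 3. It was 3 without colon replicate 1, 2 without the library labelled colon and 1 without colon replicate 4. Of the 12 named genes called, 7, 1, 1, 2, 2 and 1 stayed called in these fits, in that order. Without colon replicate 1 these were Thsd7a and Cysltr2, beside Gm41414, which lay outside the rule and was named after its values were seen. Cysltr2 was the 1 named gene called with each library left out, and the 1 gene called without small intestine replicates 2 or 3 or colon replicate 4. When the spread was estimated from these 6 libraries alone, edgeR called 0 genes, Cysltr2 included, with 573 genes at an unadjusted p under 0.05. DESeq2 called 155 in its fit of all 11 libraries, 70 higher and 85 lower, with less of a lean to lower calls. In the fits that lost their calls the folds stayed close to those with all libraries, at -2.46 to -2.97 for Ano2, 2.11 to 2.37 for Ahr and -3.00 to -3.44 for Dapk2. The lost calls therefore do not show that 1 library carried these folds. With the term for library number 1 gene, Cysltr2, was called, and 11 of the 12 named genes lost their call. All colonic libraries were numbered under 50, as were small intestine replicates 1 and 2 but not 3.

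Of 34 gene lists fixed beforehand, 7 were called in colon against small intestine by camera with a preset correlation of 0.01 and 0 with an estimated correlation, the smallest adjusted p being 0.776. The 29 voltage-gated sodium and calcium channel genes lay lower in colon as a set (adjusted p = 0.011, and adjusted p = 0.776 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. The 20 Hox genes, which encode positional transcription factors, lay lower (adjusted p = 0.0295, and adjusted p = 0.861 with an estimated correlation), as did the 13 of paralogue groups 1 to 5 (adjusted p = 0.0119, and adjusted p = 0.776 with an estimated correlation). Among them 0 were called over all genes and 1 was lower adjusted over the list alone. Markers of other cells lay higher in colonic neurons. Smooth muscle markers summed to 1399 ± 1138 against 573 ± 408 CPM (adjusted p = 0.0139, and adjusted p = 0.776 with an estimated correlation). Fibroblast markers summed to 66.8 ± 35.2 against 35.4 ± 24.4 CPM (adjusted p = 0.00405, and adjusted p = 0.776 with an estimated correlation), and those of lymphatic endothelium to 13.5 ± 11.8 against 2.49 ± 1.02 CPM (adjusted p = 1.47e-05, and adjusted p = 0.776 with an estimated correlation). The 77 ribosomal protein genes summed to 4561 ± 3521 against 3470 ± 2435 CPM (adjusted p = 0.0148, and adjusted p = 0.861 with an estimated correlation), with 0 members called. Among the 24 enteric transcription factors 1, Tbx2, was lower over all genes and 1 adjusted over the list alone. The set was not called (adjusted p = 0.378).

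Stomach was compared with small intestine in the same layer. Cdh8, a cadherin of cell adhesion, averaged 4.44 ± 0.828 CPM in stomach (SD, n = 5) and 252 ± 87.3 CPM in small intestine (n = 3), a log2 fold change of -5.83 (SE 0.25, adjusted p = 2.42e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ano2 averaged 8.46 ± 2.07 against 229 ± 86.9 CPM (-4.76, SE 0.29, adjusted p = 3.79e-05). Adgrg6 averaged 13.8 ± 5.09 against 297 ± 31.1 CPM (-4.42, SE 0.39), and Mgat4c 52.2 ± 22.9 against 941 ± 239 CPM (-4.17, SE 0.38). Ntrk3, the neurotrophin receptor TrkC, averaged 57.2 ± 10.7 against 632 ± 261 CPM (-3.46, SE 0.32, adjusted p = 0.000545). Hoxc4 averaged 2.80 ± 0.682 against 42.2 ± 11.4 CPM (-3.93, SE 0.29, adjusted p = 0.000197). Higher in stomach was Dcc, a netrin receptor, at 418 ± 109 against 82.2 ± 14.1 CPM (2.35, SE 0.31, adjusted p = 0.0053). Kctd16, an auxiliary subunit of GABA-B receptors, averaged 299.7 ± 68.1 against 63.8 ± 15.8 CPM (2.23, SE 0.29, adjusted p = 0.00489). Of 18413 genes, 140 were called, 29 higher and 111 lower in stomach. Pooled CPM was higher in non-neuronal nuclei than in neurons for 66 of the 140, against 65.9% of all genes tested, among them Hoxc4 (45.1 against 20.8 CPM), Ltbp1 (447 against 48.8) and Cacna2d3 (333 against 118). Cdh8, Ano2 and Adgrg6 lead the sensory-like neuron cluster, whose share was 1.69% in stomach and 9.80% in small intestine, so their level and that share are not independent. The fitted folds of 56.9, 27.1 and 21.4 compare with a ratio of 5.79 for the share, and no test set them against each other. In clustering without library correction Mgat4c, Dapk2 and Otof were also among the leading genes of sensory-like clusters, so their levels may depend on that share too. Not called were Elavl4 (0.24, SE 0.21, adjusted p = 0.751), Elavl3 (-0.34, SE 0.40), Nos1 (0.42, SE 0.38), Vip (0.80, SE 0.63), Chat (0.30, SE 0.24) and Tac1 (0.26, SE 0.82).

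Cdh8 (ENSMUSG00000036510) lies on chromosome 8 of mm10 from 99024471 to 99416471, and Mgat4c (ENSMUSG00000019888) on chromosome 10 from 101681487 to 102391469. Ntrk3 (ENSMUSG00000059146) lies on chromosome 7 from 78175959 to 78738012, Hoxc4 (ENSMUSG00000075394) on chromosome 15 from 103018934 to 103036852, and Dcc (ENSMUSG00000060534) on chromosome 18 from 71253634 to 72351069. Of the 37 named genes called between stomach and small intestine, 19 were called with each library left out, namely Cdh8, Ano2, Adgrg6, Mgat4c, Ntrk3, Hoxc4, Kctd16, Cdh6, Robo2, Grin3a, Scn11a, Scn7a, Tbx2, Dlx3, Dapk2, Otof, Rph3a, Adamts14 and Cbln2. The call of Dcc ended without small intestine replicate 1 (adjusted p = 0.067). Erbb4 was no longer called without small intestine replicates 1 or 3 or without stomach replicates 2, 3, 4 or 5 (adjusted p between 0.05 and 0.199). The count of 140 became 64 without small intestine replicate 1, 58 without replicate 3, 66 without stomach replicate 2, 70 without replicate 3, 78 without replicate 4 and 59 without replicate 5. In these fits 21, 24, 22, 23, 25 and 22 of the 37 named genes stayed called. It was 176 when the library labelled colon was left out of the shared fit, 57 higher and 119 lower, and 43 with antrum as the only gastric region. The lean to lower calls was weaker with DESeq2, which called 259 higher and 307 lower.

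The lists divided the changes between stomach and small intestine as follows. Of 38 ligand-gated ion channel genes, 1 was higher and 3 were lower over all genes, and 1 and 8 adjusted over the list alone (set adjusted p = 0.079). The glycine receptor subunit Glra2 (3.42, SE 0.57) was higher. The NMDA receptor subunit Grin3a (-2.84, SE 0.29) and the serotonin receptor subunit Htr3b (-1.77, SE 0.25) were among the lower ones. Of 29 sodium and calcium channel genes, 0 were higher and 3 were lower over all genes, namely Scn11a (-3.20, SE 0.38), Scn7a (-1.91, SE 0.28) and Cacna2d3 (-2.84, SE 0.51). Adjusted over the list alone there were 1 and 4 (set adjusted p = 0.0303, and adjusted p = 0.71 with an estimated correlation). Of 75 potassium channel genes, Kcna7 (3.53, SE 0.60) was the 1 called over all genes, against 4 higher and 2 lower adjusted over the list alone (set adjusted p = 0.403). Of 60 axon guidance and adhesion genes, 2 were higher and 6 lower, and 14 and 9 adjusted over the list alone (set adjusted p = 0.938). Dcc was among the higher and Cdh6 (-3.16, SE 0.29) and the Slit receptor Robo2 (-1.89, SE 0.25) among the lower. Of 15 transmitter genes, the vesicular glutamate transporter Slc17a6 (-3.14, SE 0.61) was the 1 called. Of these, 0 and 2 were higher and lower adjusted over the list alone. Of 14 genes in the list named for GDNF and endothelin signalling, Erbb4 (5.14, SE 0.94) was higher and Ntrk3 lower over all genes, and 1 and 2 adjusted over the list alone. These called genes encode a neuregulin and a neurotrophin receptor, which that list also holds.

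The Hox genes tested lay lower in gastric than in small intestinal neurons, at 257 ± 62.8 against 473 ± 89.6 summed CPM over 20 genes (adjusted p = 1.34e-11, and adjusted p = 0.331 with an estimated correlation). Hoxc4 and Hoxc5 were lower over all genes, and 8 adjusted over the list alone. Paralogues 1 to 5 (13 genes) gave adjusted p = 1.34e-11, and adjusted p = 0.331 with an estimated correlation. Paralogues 6 to 9 (7 genes) gave adjusted p = 0.0267, and adjusted p = 0.71 with an estimated correlation. Among 24 enteric transcription factors 4 were lower over all genes, namely Tbx2 (-1.84, SE 0.18), Dlx3 (-3.92, SE 0.51), Zfhx3 (-2.15, SE 0.40) and Neurod6. Neurod6 had 2 UMIs in stomach and 398 in small intestine (ratio 171, 95% counting interval 46.9 to 1413). Adjusted over the list alone, 1 factor was higher and 4 were lower. The set lay lower (adjusted p = 0.0356, and adjusted p = 0.349 with an estimated correlation) although its summed CPM did not. Markers of gastric epithelium summed to 117.6 ± 108 CPM in gastric neurons and 7.47 ± 8.13 CPM in small intestinal ones (adjusted p = 0.000336, and adjusted p = 0.546 with an estimated correlation). Of them, 0 were called over all genes and 4 were higher adjusted over the list alone. Markers of lymphatic endothelium summed to 7.56 ± 5.18 against 2.49 ± 1.02 CPM (adjusted p = 0.0388, and adjusted p = 0.71 with an estimated correlation). In all, 7 of 34 lists were called with the preset correlation and 0 with an estimated one.

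Stomach was also compared with colon. Cdh8 averaged 4.44 ± 0.828 CPM in stomach (n = 5) and 95.3 ± 12.4 CPM in colon (n = 3), a log2 fold change of -4.43 (SE 0.24, adjusted p = 3.2e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Htr7, a serotonin receptor, averaged 1.84 ± 1.46 against 96.0 ± 22.4 CPM (-5.68, SE 0.61, adjusted p = 0.00627). Zfp804b averaged 2.97 ± 1.93 against 117 ± 21.3 CPM (-5.28, SE 0.51, adjusted p = 0.00506), and Amigo2 1.12 ± 0.195 against 22.7 ± 14.3 CPM (-4.32, SE 0.44, adjusted p = 0.00592). The POU transcription factor gene Pou3f3 averaged 0.38 ± 0.508 against 44.0 ± 19.7 CPM (-6.86, SE 1.18, adjusted p = 0.0415) and its neighbour Pantr2 0.235 against 21.2 CPM. Since these genes lie side by side without a stated strand rule their counts are not independent. Ntrk3 averaged 57.2 ± 10.7 against 429 ± 190 CPM (-2.91, SE 0.31, adjusted p = 0.00627) and Col25a1 18.3 ± 11.54 against 438 ± 188 CPM (-4.58, SE 0.72). Neto1 (-3.00), Adamts2 (-2.94) and Pdgfd (-3.21), the last with 149 CPM in non-neuronal nuclei, were also lower. The 2 genes higher in stomach were Hpcal1 (1.28, SE 0.22) and Kcna7 (3.82, SE 0.61), and 60 of 18413 were lower. Not called were Elavl4 (0.20, SE 0.21), Elavl3 (-0.08, SE 0.40), Nos1 (-0.38, SE 0.37), Vip (0.45, SE 0.62), Chat (0.61, SE 0.24) and Tac1 (-0.92, SE 0.80). Htr7 (ENSMUSG00000024798) lies on chromosome 19 of mm10 from 35958734 to 36057507. Zfp804b (ENSMUSG00000092094) lies on chromosome 5 from 6769010 to 7344756, and Pou3f3 (ENSMUSG00000045515) on chromosome 1 from 42695768 to 42703176.

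Without the library labelled colon, 256 genes were called between stomach and colon, 86 higher and 170 lower, and all 62 were among them. The count fell to 9 without colon replicate 1, 7 without colon replicate 4 and 38 without stomach replicate 1. It fell to 5 without stomach replicate 2, 8 without replicate 3, 6 without replicate 4 and 5 without replicate 5. In these fits 5, 5, 11, 5, 5, 4 and 5 of the 16 named genes stayed called. Cdh8, Htr7, Zfp804b and Amigo2 were called in each of them. Cdh8 alone of the named genes was also called under each other setting, and it was the 1 gene called with antrum as the only gastric region. It was also the 1 gene called with the term for library number, where 15 of the 16 named genes lost their call. All colonic libraries were numbered under 50 and all gastric ones except antrum replicate 1 higher. That term therefore cannot be separated well from organ here.

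Among 20 Hox genes, Hoxc4 (2.80 ± 0.682 against 12.5 ± 3.65 CPM, -2.17, SE 0.28, adjusted p = 0.0163 by edgeR) was the 1 called lower in stomach than in colon, against 6 lower adjusted over the list alone. The Hox set lay lower (adjusted p = 7.62e-06, and adjusted p = 0.796 with an estimated correlation). Paralogues 1 to 5 lay lower too (adjusted p = 3.02e-05, and adjusted p = 0.796 with an estimated correlation). The 38 ligand-gated channel genes lay lower (adjusted p = 0.0229, and adjusted p = 0.852 with an estimated correlation), with 0 called and 6 lower adjusted over the list alone. Scn11a (-2.50, SE 0.38) was the 1 sodium or calcium channel gene called, against 2 lower adjusted over the list alone. Htr7 was the 1 neuromodulator receptor called, against 3. Slc17a6 averaged 0.613 ± 0.538 against 11.8 ± 5.38 CPM (-4.15, SE 0.62) and was the 1 transmitter gene called, against 1 higher and 1 lower adjusted over the list alone. The ribosomal protein genes summed to 2768 ± 1049 in stomach and 4561 ± 3521 CPM in colon (adjusted p = 0.00569, and adjusted p = 0.972 with an estimated correlation). Gastric epithelial markers summed to 117.6 ± 108 and 14.3 ± 21.04 CPM (adjusted p = 0.000843, and adjusted p = 0.796 with an estimated correlation). In all, 5 of 34 lists were called with the preset correlation and 0 with an estimated one.

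**Figure D2:**
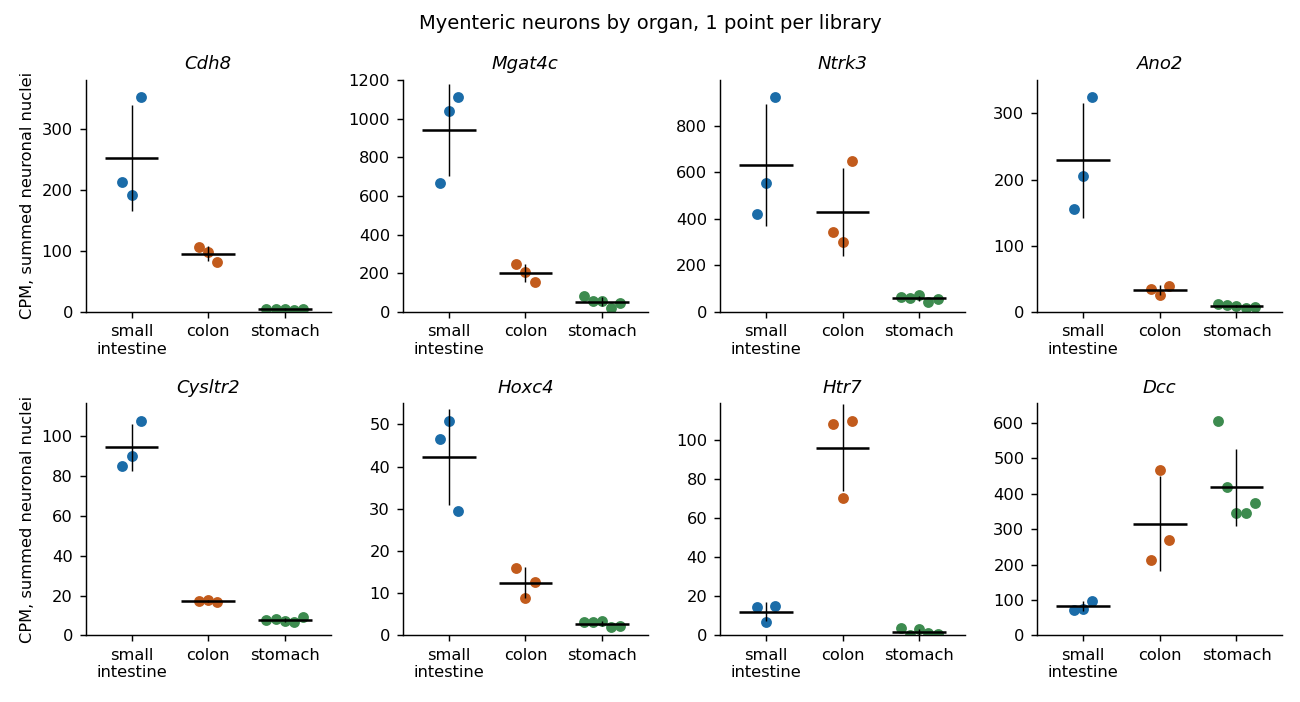
CPM of 8 genes in neurons of each myenteric library (points), with the mean (bar) and SD (vertical line) of small intestine (n = 3), colon (n = 3) and stomach (n = 5), after TMM scaling. Cdh8 averaged 252 CPM in small intestine, 95.3 in colon and 4.44 in stomach, and Htr7 averaged 96.0 CPM in colon against 1.84 in stomach.

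Neuron clusters were named as motor-like, interneuron-like and sensory-like classes from markers fixed beforehand, and shares of neurons were compared by exact two-sided permutation tests adjusted over 20 tests, none of which passed. The sensory-like class made up 9.80% ± 1.11 of neurons in small intestine (SD, n = 3), 2.55% ± 0.759 in colon (n = 3, exact p = 0.1, the smallest that 3 against 3 can give, adjusted p = 0.182). It made up 1.69% ± 0.7105 of neurons in stomach (n = 5, exact p = 0.0179 against small intestine, the smallest that 5 against 3 can give, adjusted p = 0.1). The inhibitory motor-like class made up 20.1% ± 1.80, 30.4% ± 6.72 and 21.7% ± 2.89 in that order of organs (exact p = 0.1 for colon against small intestine, 0.536 for stomach against small intestine, and 0.0357 with adjusted p = 0.102 for stomach against colon). The excitatory motor-like class made up 46.1% ± 2.22, 42.5% ± 0.598 and 47.0% ± 9.80. The interneuron-like class made up 5.37% ± 0.690, 6.32% ± 0.439 and 8.67% ± 1.10 (exact p = 0.0179 for stomach against small intestine, adjusted p = 0.1). In the submucosal layer (n = 3, small intestine and colon, permuted within organ) the excitatory class made up 15.3% ± 6.78 against 44.3% ± 2.47 in the intestinal myenteric layer (n = 6, exact p = 0.025, the smallest possible here, adjusted p = 0.1). There the interneuron-like class made up 1.58% ± 0.0284 against 5.85% ± 0.734, and the sensory-like class 11.2% ± 4.53 against 6.17% ± 4.06, each with exact p = 0.025 and adjusted p = 0.1. The inhibitory class made up 25.3% ± 5.19 and 25.3% ± 7.15 (exact p = 0.575). The layers were compared within organ, where the differences were -29.6 percentage points for the excitatory, 1.71 for the inhibitory, -4.11 for the interneuron-like and 3.87 for the sensory-like share, which are not the differences of these means. In the inhibitory class its marker Nos1 stood at 100.04, 5.69 and 9.86 CPM in the submucosal libraries against 1011 to 3905 CPM in the intestinal myenteric ones. Vip, another of its markers, stood there at 1453, 1142 and 776 CPM against 47.2 to 362 CPM. Vip also marks a secretomotor or vasodilator class fixed beforehand, for which no cluster was named with library correction. Without correction 1 cluster was, with 89.3% of its nuclei from submucosal colon. Like shares of this class therefore do not show that inhibitory motor neurons were equally common in both layers. Directions of 3 of the 20 differences changed at Leiden resolution 2. The excitatory difference in stomach against small intestine turned to -2.04 percentage points, the sensory-like one in stomach against colon to 0.231 and the inhibitory one between the layers from 1.71 within organ to -0.0432, and to -2.27 with at least 1000 genes per nucleus. The first was also below 0 without small intestine replicate 1 (-0.162) or stomach replicates 1 (-1.25) or 3 (-1.85). Clusters left unnamed under a score minimum set after the data were seen held 46.6% ± 6.27 of submucosal (n = 3) and 18.4% ± 4.12 of intestinal myenteric neurons (n = 6), and 21.01% ± 6.09 of gastric ones (n = 5). The sort on HuC/D and the depth gap between libraries can set such shares. Clustering without library correction could not test the inhibitory and interneuron-like shares. The 3 clusters named inhibitory there drew 90.35% to 100% of their nuclei from ileum replicate 1, and clusters led by other libraries stayed unnamed with Nos1 at up to 3737 CPM. For the interneuron-like class 1 cluster was named, and 2 others that scored highest for it were not.

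**Figure D3:**
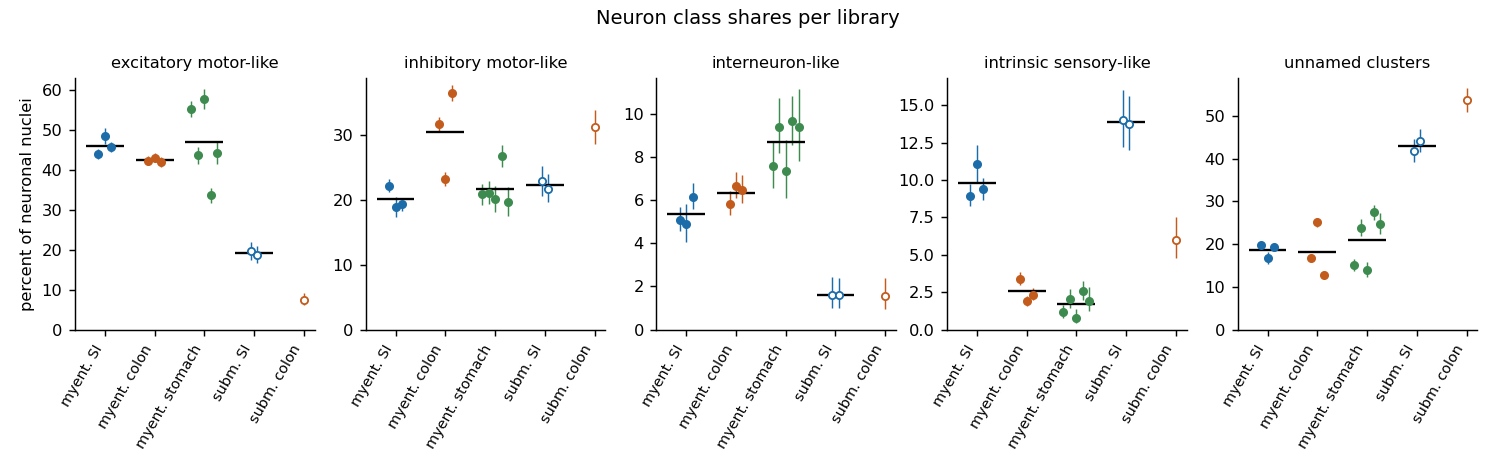
Share of neurons in the 4 named classes and in unnamed clusters, per library (points with exact 95% binomial intervals, counting error only) and as group means (black bars, in groups of at least 2 libraries), in percent. The sensory-like share averaged 9.80% in myenteric small intestine, 2.55% in colon and 1.69% in stomach.

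Within the inhibitory motor-like class 316 genes were called between stomach (n = 5) and colon (n = 3), 177 higher and 139 lower in stomach. Pou3f3 had 3 UMIs in stomach and 776 in colon (ratio 217, 95% counting interval 73.9 to 1054). Sst, which encodes somatostatin, averaged 0.248 ± 0.349 against 164 ± 209 CPM (log2 fold change -8.64, SE 1.45, adjusted p = 0.0146 by edgeR). The adrenergic receptor gene Adra1a averaged 22.3 ± 12.4 against 0.638 ± 0.714 CPM (5.04, SE 0.81, adjusted p = 0.0128). These and Pantr2 were called with each library left out. The count was 169, 148 and 108 without colon replicate 1, the library labelled colon or colon replicate 4, and 141 and 104 without stomach replicates 2 or 5. The lean to higher calls turned without these colonic libraries, to 71 higher and 98 lower, 68 and 80, and 50 and 58 in that order, and DESeq2 called 479 higher and 301 lower. The Sst transcripts in colon were not particular to this class. Without TMM scaling they stood at 438, 68.6 and 12.8 CPM in it in colon replicate 1, the library labelled colon and colon replicate 4, and at 768, 204 and 31.3 CPM in smooth muscle nuclei of these libraries. Of 12 neuropeptide genes in this class 3, Sst, Nmu and Calcb, were lower in stomach and 5 adjusted over the list alone (set adjusted p = 0.00763, and adjusted p = 0.795 with an estimated correlation). Nmu stood at 59.6, 36.5 and 9.06 CPM in the class and 93.1, 114 and 21.4 CPM in smooth muscle nuclei of the 3 colonic libraries, and Calcb at 140.05, 18.5 and 3.59 against 243, 53.2 and 8.69 CPM, so these calls are not read as expression by the class. Of 58 axon guidance genes 5 were higher and 3 lower, and 15 and 6 adjusted over the list alone (set adjusted p = 0.00763, and adjusted p = 0.795 with an estimated correlation). Against small intestine, 50 genes were called in gastric inhibitory neurons (20 higher, 30 lower). Chrna7, a nicotinic receptor subunit, averaged 10.1 ± 3.56 against 169 ± 62.4 CPM (-4.04, SE 0.51, adjusted p = 0.024), and Hoxc4 (-3.98, SE 0.58) was also lower. That count was 0 without small intestine replicates 1 or 3 or without stomach replicates 2 or 5, and 126 without small intestine replicate 2. It was 29, 28 and 16 without stomach replicates 1, 3 and 4, and 26 when the library labelled colon was left out of the shared fit. The lean to lower calls was not kept, with 14 higher and 2 lower without stomach replicate 4, 17 and 11 without replicate 3, 14 and 12 in the shared fit without the library labelled colon, and 212 and 132 by DESeq2. Accordingly 0 of the 6 named genes were called with each library left out. Between colon and small intestine 6 genes were called. Cpne4 averaged 206 ± 18.3 against 25.8 ± 13.5 CPM (3.00, SE 0.38, adjusted p = 0.0188). The others were Pcdh19 (2.11), Slc38a11 (-4.03), Pde4b (-2.65), Adgrl2 (-2.54) and, outside the naming rule and named after its values were seen, Spon1 (-1.95, SE 0.22). This count became 8, 0 and 3 without small intestine replicates 1, 2 and 3 and 19 (13 higher, 6 lower), 1 and 0 without colon replicate 1, the library labelled colon and colon replicate 4. Clusters 1 and 3 held most of this class, at 9.37% and 9.39% of neurons in stomach, 11.005% and 7.51% in small intestine and 16.3% and 10.3% in colon.

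Within the excitatory motor-like class, Zfp804b averaged 1.79 ± 0.849 CPM in stomach (n = 5) and 188 ± 54.8 CPM in colon (n = 3, log2 fold change -6.68, SE 0.66, adjusted p = 0.00535 by edgeR) and was called with each library left out. Htr7 averaged 2.46 ± 1.98 against 162 ± 28.6 CPM (-5.96, SE 0.75, adjusted p = 0.018) and Pou3f3 0.253 ± 0.421 against 36.0 ± 16.8 CPM (-7.21, SE 1.07). In this class 28 genes were called between stomach and colon, all lower in stomach. The count was 137 without the library labelled colon, 62 higher and 75 lower, so the absence of higher calls depended on that library. DESeq2 called 99 higher and 196 lower. The count was 6 and 5 without colon replicates 1 and 4, and 11, 6, 4, 3 and 2 without stomach replicates 1 to 5. Against small intestine 49 were called, 31 higher and 18 lower. Ntm averaged 93.1 ± 47.8 against 4.64 ± 2.77 CPM (4.30, SE 0.64, adjusted p = 0.0325) and Hoxc4 3.33 ± 1.497 against 34.9 ± 14.1 CPM (-3.44, SE 0.42, adjusted p = 0.016). That count was 1, 31 and 1 without small intestine replicates 1, 2 and 3, and 32, 5, 13, 8 and 0 without stomach replicates 1 to 5. It was 114 when the library labelled colon was left out of the shared fit, 86 higher and 28 lower, but 12 were higher and 19 lower without small intestine replicate 2. Of 60 axon guidance genes 1 was higher and 0 lower in stomach, and 10 and 1 adjusted over the list alone (set adjusted p = 2.6e-06, and adjusted p = 0.611 with an estimated correlation). Of 16 Hox genes 0 were higher and 1 was lower, and 0 and 7 adjusted over the list alone (set adjusted p = 1.34e-09, and adjusted p = 0.239 with an estimated correlation). The 1 gene called between colon and small intestine was Erbb4, a neuregulin receptor, at 55.5 ± 7.39 against 4.18 ± 0.677 CPM (3.73, SE 0.40, adjusted p = 0.0265). Its call was kept without colon replicate 4, where 2 genes were called, Erbb4 and, outside the rule and named after its values were seen, Glra2. It ended in each fit without another of these 6 libraries (adjusted p of Erbb4 0.0393 in the former and 0.0565 to 0.161 in the latter). Without the library labelled colon 1 gene was called, Wnk4 (5.20, adjusted p = 0.0448), and without small intestine replicate 3 it was Flrt2 (3.42, adjusted p = 0.0257), both outside the rule and named after their values were seen. Without small intestine replicates 1 or 2 or colon replicate 1 the count was 0. Clusters 0 and 2 together held most of this class, at 15.0% and 11.998% of neurons in stomach, 23.8% and 9.46% in small intestine and 15.9% and 10.1% in colon.

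Submucosal neurons were compared with myenteric neurons of small intestine and colon, with organ as a term. Kcnd2, an A-type potassium channel, averaged 8546 ± 1600 CPM in the submucosal libraries (SD, n = 3) and 1819 ± 389 CPM in the myenteric ones (n = 6), a log2 fold change of 2.23 (SE 0.25, adjusted p = 0.0031 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The semaphorin receptor gene Plxna4 averaged 2241 ± 781 against 385 ± 141 CPM (2.39, SE 0.28, adjusted p = 0.00359). Scgn, which encodes the calcium-binding protein secretagogin, averaged 233 ± 46.0 against 22.5 ± 7.86 CPM (3.39, SE 0.31, adjusted p = 0.00154). Dbh, the enzyme that makes noradrenaline from dopamine, averaged 47.6 ± 22.3 against 7.55 ± 3.73 CPM (2.85, SE 0.29). Npr1, a natriuretic peptide receptor, averaged 31.9 ± 14.4 against 1.10 ± 0.571 CPM (4.85, SE 0.45), with 10.9 CPM in non-neuronal nuclei against 4.75 in neurons over the pooled libraries. Lower in the submucosal layer was Nos1, the neuronal nitric oxide synthase, at 39.0 ± 39.1 against 765 ± 485 CPM (-4.39, SE 0.76, adjusted p = 0.0127). Oprk1, the kappa opioid receptor, averaged 2.60 ± 1.60 against 93.3 ± 35.0 CPM (-5.25, SE 0.58, adjusted p = 0.00308), and Cdh12 15.2 ± 3.29 against 216 ± 66.1 CPM (-3.79, SE 0.35, adjusted p = 0.00154). Epha8, an ephrin receptor gene, averaged 0.560 ± 0.358 against 37.6 ± 17.9 CPM (-6.01, SE 0.72), and Kcnip4, an auxiliary subunit of A-type channels, 699 ± 937 against 11144 ± 5945 CPM (-4.35, SE 0.61, adjusted p = 0.00607). Of 17134 genes, 1113 were called, 412 higher and 701 lower. Groups did not overlap for 1106 of them, against 27.0% of the genes tested and 5% by chance. The HuC/D genes Elavl3 (-0.18, SE 0.43) and Elavl4 (-0.05, SE 0.24, and 0.04 with DESeq2's size factors) were not called. Layer and nuclear isolation buffer went together in these libraries, so these tests cannot separate them.

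Kcnd2 (ENSMUSG00000060882) lies on chromosome 6 of mm10 from 21215503 to 21729805, Plxna4 (ENSMUSG00000029765) on chromosome 6 from 32144268 to 32588192, Scgn (ENSMUSG00000021337) on chromosome 13 from 23953456 to 23991214. Nos1 (ENSMUSG00000029361) lies on chromosome 5 from 117781032 to 117958840, Oprk1 (ENSMUSG00000025905) on chromosome 1 from 5588466 to 5606131, and Cdh12 (ENSMUSG00000040452) on chromosome 15 from 20449265 to 21589533. Of the 65 named genes called between the layers, 30 were called with each library left out. They were Kcnd2, Kcnj3, Kcnk13, Plxna4, Scgn, Dbh, Npr1, Tacr1, Etv1, Dlx3, Nr4a3, Clec14a, Arsi, Gpc3, Lmo7 and Adam12 among the higher and Oprk1, Galr1, Calcrl, Htr2b, Chrna7, Gabrg3, Cdh12, Epha5, Epha8, Unc5d, Dsc3, Fbxw15, Fbxw24 and Des among the lower ones. Nos1 was not called without submucosal small intestine replicate 2 (-4.64, adjusted p = 0.0787), nor was Kcnip4 (-4.22, adjusted p = 0.0572). The count of 1113 became 634 without submucosal colon, 222 (111 higher, 111 lower) and 192 (98 higher, 94 lower) without submucosal small intestine replicates 1 and 2, 647 without myenteric small intestine replicate 1 and 723 without replicate 3. In those fits 44, 34, 32, 53 and 57 of the 65 named genes stayed called. It was 997 without the library labelled colon, 461 with a term for the library number and 645 in small intestine alone.

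**Figure D4:**
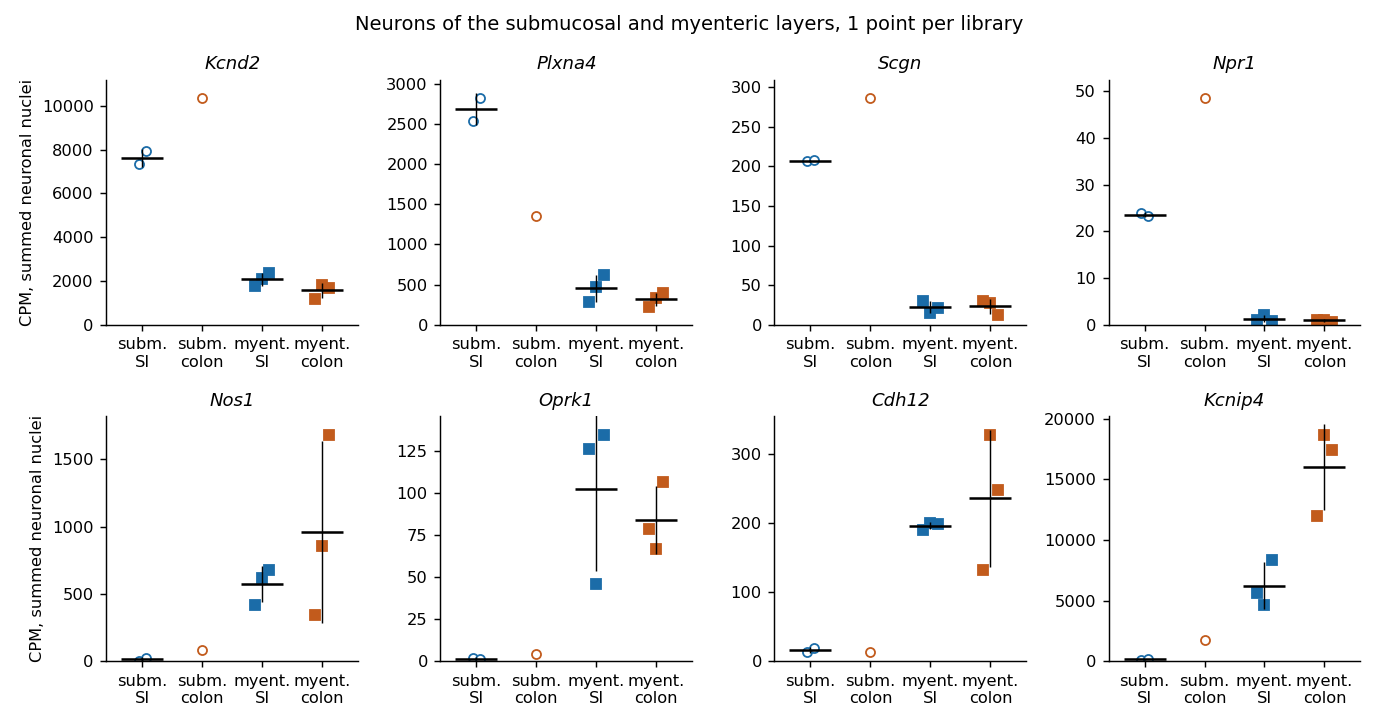
CPM of 8 genes in neurons of submucosal small intestine (n = 2), submucosal colon (n = 1), myenteric small intestine (n = 3) and myenteric colon (n = 3), 1 point per library, with means (bars) and SDs (vertical lines) in groups of at least 2, after TMM scaling. Kcnd2 averaged 8546 CPM over the submucosal and 1819 over the myenteric libraries, and Oprk1 2.60 and 93.3.

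Potassium channel genes moved both ways between the layers, 6 of 69 higher and 7 lower over all genes, and 8 and 14 adjusted over the list alone (set adjusted p = 0.984). Kcnj3, an inward rectifier, averaged 1204 ± 152 against 363 ± 74.8 CPM (1.75, SE 0.20, adjusted p = 0.00311 by edgeR) and Kcnk13 119 ± 40.3 against 20.7 ± 7.63 CPM (2.55, SE 0.34). Of 37 neuromodulator receptor genes 7 were higher and 12 lower, and 7 and 15 adjusted over the list alone (set adjusted p = 0.235). Tacr1, the substance P receptor, averaged 186 ± 151 against 20.2 ± 13.1 CPM (3.24, SE 0.43), with 69.5 CPM in non-neuronal nuclei against 37.1 in neurons. Galr1 (-3.08, SE 0.29), the CGRP receptor component Calcrl (-2.50, SE 0.26) and the serotonin receptor Htr2b (-3.75, SE 0.46) were lower. Of 37 ligand-gated channel genes 2 were higher and 3 lower, and 2 and 7 adjusted over the list alone. Chrna7 averaged 9.18 ± 0.844 against 175 ± 85.1 CPM (-4.22, SE 0.57, adjusted p = 0.00536) and Gabrg3 225 ± 144 against 1120 ± 334 CPM (-2.30, SE 0.29). The 60 axon guidance genes, 8 higher and 15 lower over all genes and 9 and 21 adjusted over the list alone, lay lower as a set (adjusted p = 0.0485, and adjusted p = 0.928 with an estimated correlation). Epha5 (-2.88, SE 0.32) and Unc5d (-2.17, SE 0.23) were among the lower ones, although the genes' summed CPM was higher in the submucosal layer. Of 22 enteric transcription factors 2 were higher, Etv1 (1.78, SE 0.20) and Dlx3 (2.03, SE 0.29), and 3 lower, and 3 and 6 adjusted over the list alone. Of 21 Hox genes Hoxc4 (1.39, SE 0.25) was higher and Hoxd3 (-1.79, SE 0.28) and Hoxd4 (-2.98, SE 0.52) were lower, with the same counts adjusted over the list alone. Since Hoxd4 lies within the Hoxd3 locus their counts can be shared.

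Of 15 neuropeptide genes 1 was higher in the submucosal layer and 2 were lower over all genes, and 1 and 4 adjusted over the list alone (set adjusted p = 0.376). Vip averaged 824 ± 369 against 149 ± 103 CPM (2.50, SE 0.59, adjusted p = 0.0381 by edgeR). Cartpt averaged 1.79 ± 1.59 against 159 ± 159 CPM (-6.43, SE 1.48, adjusted p = 0.0355), and Grp, which encodes gastrin-releasing peptide, 1.72 ± 1.89 against 86.2 ± 116 CPM (-5.07, SE 1.25, adjusted p = 0.0438). In the same libraries pooled, non-neuronal nuclei held 417 CPM of Vip against 266 in neurons, 317 against 162 of Cartpt, and 102 against 67.9 of Grp. The Vip call ended without colon replicate 1, the library labelled colon, small intestine replicates 2 or 3 or any submucosal library (adjusted p between 0.0514 and 0.191). That of Cartpt ended without small intestine replicate 1, colon replicate 1, the library labelled colon or any submucosal library (0.0512 to 0.16), and that of Grp ended in each such fit except that without colon replicate 4 (0.0515 to 0.179). Of 15 transmitter genes 1 was higher and 5 lower, and 2 and 8 adjusted over the list alone (set adjusted p = 0.052). Among the lower ones were Slc17a6 (-4.16, SE 0.74), Gad1 with 3 UMIs against 323 (ratio 16.4, 95% counting interval 5.56 to 79.8) and Chat (81.8 ± 39.1 against 172 ± 44.4 CPM, -1.28, SE 0.32, adjusted p = 0.0475). The Chat call was kept only without colon replicates 1 or 4 (other fits 0.0584 to 0.228), and it ended with DESeq2's size factors (0.0579). Tac1 averaged 24.1 ± 39.7 against 227 ± 227 CPM and was not called (-4.23, SE 1.42, adjusted p = 0.103).

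The 12 immediate early genes, which neurons transcribe after activity or handling, lay higher in the submucosal layer as a set (adjusted p = 0.00189, and adjusted p = 0.565 with an estimated correlation). Of them 3 were called over all genes and 4 adjusted over the list alone. Nr4a3 averaged 37.7 ± 3.37 against 4.42 ± 1.51 CPM (3.11, SE 0.30, adjusted p = 0.0019 by edgeR) and was called with each library left out. Npas4 (1.60, SE 0.35) and Egr1 (2.09, SE 0.51) were lost in 5 and 6 of the 9 such fits. The 7 smooth muscle markers summed to 18.9 ± 11.7 against 922 ± 777 CPM (adjusted p = 2.23e-08, and adjusted p = 0.474 with an estimated correlation), with 5 lower over all genes and 7 adjusted over the list alone. Myh11 averaged 7.62 ± 4.29 against 274 ± 165 CPM (-5.10, SE 0.72) and stood at 2641 CPM in non-neuronal nuclei. The 77 ribosomal protein genes lay lower (1442 ± 190 against 3802 ± 2432 CPM, adjusted p = 1.38e-06, and adjusted p = 0.928 with an estimated correlation), with Rpl21, a gene with many pseudogene copies, as the 1 called. The myenteric mean came from 3 libraries, ileum replicate 1, proximal colon replicate 1 and the library labelled colon, where these genes took 0.657%, 0.842% and 0.353% of neuronal UMIs. The other 3 myenteric libraries (0.141% to 0.212%) lay close to the submucosal ones (0.114% to 0.157%). Pooled CPM was higher in non-neuronal nuclei for 577 of the 1113 called genes, against 68.2% of all genes tested, among them the goblet cell gene Itln1 (114 against 6.47 CPM) and Igha (48.7 against 4.65), both higher in submucosal neurons. The paired family members Fbxw15 (-5.57, SE 0.69) and Fbxw24 (-5.48, SE 0.43) were lower, but reads can be shared within that family. In all, 4 of 34 lists were called with the preset correlation and 0 with an estimated one.

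Within the stomach, antrum (n = 3) was compared with corpus and fundus (n = 2). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 19212 genes were called, with 429 at an unadjusted p under 0.05, and DESeq2 called 1, Fbxw24 (log2 fold change 5.30), named after its values were seen. Nos1 averaged 691 ± 46.0 CPM in antrum and 872 ± 52.1 CPM in corpus and fundus (-0.34, SE 0.48), and Vip 238 ± 56.8 and 237 ± 145 CPM (0.01, SE 0.81). Chat averaged 252 ± 35.4 and 217.5 ± 72.0 CPM (0.21, SE 0.30) and Tac1 199.9 ± 54.8 and 145 ± 114 CPM (0.46, SE 1.076). Elavl3 averaged 345 ± 33.8 and 404 ± 148 CPM (-0.23, SE 0.52) and Elavl4 1258 ± 131 and 1114 ± 251 CPM (0.18, SE 0.27), and each of these 6 genes had adjusted p = 1. The excitatory motor-like share was 52.5% ± 7.17 in antrum and 38.7% ± 7.10 in corpus and fundus (exact permutation p = 0.2, where 0.1 is the smallest possible). The inhibitory one was 20.2% ± 0.611 and 23.9% ± 4.01 (exact p = 0.1, adjusted p = 0.182). With the preset correlation 9 of 35 lists were called, 7 higher and 2 lower in antrum, and 0 with an estimated one. Of their members 0 were called over all genes or adjusted over the list alone. The 60 axon guidance genes gave adjusted p = 2.58e-08, and adjusted p = 0.719 with an estimated correlation. The 37 neuromodulator receptors gave adjusted p = 0.00615, and adjusted p = 0.193 with an estimated correlation, and the 25 Hox genes adjusted p = 0.00968, and adjusted p = 0.719 with an estimated correlation, all higher in antrum. Antrum was also higher for Hox paralogues 1 to 5 (adjusted p = 0.000402), neuropeptides (0.0065), immediate early genes (0.0213) and intestinal epithelial markers (0.00968). It was lower for ribosomal protein genes (0.000525) and mesothelial markers (0.0257). All of these lists had adjusted p = 0.719 or 0.903 with an estimated correlation. The neuropeptides' summed CPM was 988 ± 181 in antrum and 1048 ± 837 in corpus and fundus, lower in antrum although the set test lay higher.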

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

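Of the tests in this part, those of free stomach RNA and of a library taken wholly from stomach were chosen only after the result was seen.

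The library labelled colon drew attention because a transcript outside the neuronal comparisons, Barx1, stood at 57.2 CPM in its smooth muscle nuclei, where the other intestinal myenteric libraries had 0 UMIs and the gastric ones 71.6 to 208 CPM. Free RNA from stomach tissue would reach all nuclei alike. Against it as the source of Barx1, that gene was 20.95 times as high in smooth muscle as in neurons (95% interval 14.4 to 30.6). Free stomach RNA beside it is not excluded. In the same smooth muscle nuclei the gastric epithelial genes Gkn1, Tff1 and Pgc summed to 161 CPM. They summed to 0 to 33.1 CPM in the other intestinal myenteric libraries and 39.7 to 1965 CPM in the gastric ones. A library taken wholly from stomach is argued against by Hox paralogues 9 to 13, at 87.6 CPM (76.9 to 99.3) against at most 14.7 CPM in gastric libraries and an upper bound of 51.2 CPM in the shallow corpus. Among its 1912 smooth muscle nuclei, 136 had a Barx1 UMI, 201 a UMI of these Hox genes and 6 both, against 17.2 by chance within 4 depth strata (odds ratio 0.276, 95% interval 0.117 to 0.649), which is consistent with nuclei of stomach and colon in 1 library. Clusters mostly of gastric libraries held 41.6% of its neurons. Htr7 (3.88 CPM there, 122 CPM elsewhere) is no separate test, as expression set the clusters. No biological cause was tested.

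Among the 5 gastric libraries, 5 values stood apart from their group by the gap to the nearest other library as a share of the range, with 57 groups tested and 2.85 such values from chance alone, which marks about 1 group in 20. The inhibitory motor-like share was highest in the fundus, at 26.7% of neurons (gap 0.798 of the range). Cacna2d3 was highest in the fundus at 70.3 CPM (0.803). Dcc was highest in antrum replicate 1 at 607 CPM (0.723). Neurod6 had UMIs only in the fundus, at 0.192 CPM (1.0 of the range). Tbx2 was highest in the corpus at 21.1 CPM (0.749).

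The layer effect differed between colon and small intestine for 5 of 17134 genes by an interaction term in edgeR with Benjamini-Hochberg adjustment, with 914 at an unadjusted p under 0.05. For 4 of them the differences, colon minus small intestine on the log2 scale, were 5.85 for Gpc5 (adjusted p = 0.00557), 5.35 for Ltk, 5.84 for Prkg1 and 6.26 for Marchf1. These 4 genes were named after their values were seen, and the term rests on the 1 submucosal colon library. The spread comes from the other groups, and without that library there is no term to fit, so a difference of that library alone is not excluded.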

How the results depend on the processing

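The automatic doublet threshold, the term for ribosomal share and the shared fit without the library labelled colon were chosen only after the data were seen, and all other alternatives were planned. For each change given here, the cause was not tested unless it follows from fewer libraries or genes. No paired analysis was possible because the labels give no replicate numbers, animals or days that tie libraries together.

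Counts of called genes by DESeq2 were 155, 566, 455, 2244 and 1 for colon against small intestine, stomach against small intestine, stomach against colon, the layers and the gastric regions, in place of 16, 140, 62, 1113 and 0, and 140, 344 and 780 in inhibitory and 95, 483 and 295 in excitatory neurons for the organ pairs in that order. On simulated data DESeq2 made 44 to 79 false calls in the all-neuron fits, against 2 to 5 by edgeR. In the class fits it made 19 to 47, against 2 to 6. Genes were drawn independently there, so these counts leave out effects shared by the genes of a library. With a term for library number the first 4 counts were 1 (Cysltr2), 73, 1 (Cdh8) and 461. Colonic myenteric libraries, like small intestine replicates 1 and 2, were all numbered under 50. Gastric ones except antrum replicate 1 were numbered higher. Organ and library number thus largely went together, and the lower counts cannot tell 1 from the other. With a term for ribosomal share 28 genes were called for colon against small intestine, and with only its own libraries in the fit 0, with 573 at an unadjusted p under 0.05. With antrum as the only gastric region 43 and 1 were called against small intestine and colon. With genes higher in non-neuronal nuclei left out, 106 were called for stomach against colon and 645 for the layers, and in small intestine alone 645 for the layers. Without the library labelled colon in the shared fit 26 inhibitory and 114 excitatory genes were called for stomach against small intestine. With an estimated correlation the lists called fell to 0 from 7, 7, 5, 4 and 9 in the all-neuron comparisons, from 6, 5 and 7 in inhibitory and from 9, 8 and 4 in excitatory neurons. All other alternatives fixed beforehand left these counts within 1.5 times.

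With 1 library left out at a time, the counts ran from 1 to 8, 58 to 178, 5 to 256, 192 to 1230 and 0 to 0 in the same order, from 0 to 19, 0 to 126 and 104 to 264 in inhibitory and from 0 to 2, 0 to 32 and 2 to 137 in excitatory neurons. Of named called genes, 1 of 12, 19 of 37, 4 of 16 and 30 of 65 were called with each library left out, and 0, 18, 1 and 40 under each other setting.

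Of the 20 share differences, 8 had the other sign under at least 1 alternative, 3 of them with library correction. Without it the difference became -12.0 percentage points for the inhibitory share in colon and in stomach against small intestine, 0.0200 in stomach against colon and -8.02 between layers, and for the interneuron-like share -1.50 and -2.99 in stomach against small intestine and colon. These values say nothing of the direction, since clusters named inhibitory there drew 90.35% to 100% of their nuclei from ileum replicate 1, clusters of other libraries with Nos1 at up to 3737 CPM stayed unnamed, and 1 of 3 clusters that scored highest for interneurons was named. At Leiden resolution 2 the excitatory share in stomach against small intestine became -2.04, the sensory-like share in stomach against colon 0.231 and the inhibitory share between layers -0.0432, and with at least 1000 genes per nucleus the last was -2.27. With 1 library left out, differences in percentage points for the excitatory, inhibitory, interneuron-like and sensory-like shares ran as follows. Colon against small intestine gave -4.66 to -2.46, 7.29 to 13.9, 0.701 to 1.34 and -7.68 to -6.63. Stomach against small intestine gave -1.85 to 4.19, 0.268 to 2.57, 3.04 to 3.69 and -8.53 to -7.48. Stomach against colon gave 1.80 to 7.84, -12.4 to -5.76, 2.10 to 2.67 and -1.17 to -0.432. The layers, compared within organ, gave -31.2 to -26.9, 0.5002 to 2.71, -4.28 to -3.78 and 3.58 to 4.28, against -29.6, 1.71, -4.11 and 3.87 with all libraries, and the gastric regions 8.84 to 18.9, -6.56 to -0.889, -2.05 to -1.05 and -1.31 to -0.724.

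Genes that were not called changed direction as follows, on the log2 scale. With the term for library number Elavl3 was at 0.075 in colon against small intestine and 0.024 between gastric regions, and Vip at -0.17 there, or -0.0084 with at least 1000 genes. With the term for ribosomal share Tac1 was at 0.27 in stomach against colon. Between layers Elavl4 was at 0.038 with DESeq2 and with its size factors, 0.10 without genes higher in non-neuronal nuclei and 0.051 in small intestine alone. With 1 library left out, Elavl3 ran from -0.86 to 0.28, Elavl4 from -0.19 to 0.21 and Vip from -0.078 to 1.54 in colon against small intestine. In stomach against small intestine Elavl3 ran from -0.61 to 0.19 and Tac1 from -0.17 to 1.70, and in stomach against colon Elavl3 from -0.40 to 0.52, Nos1 from -0.76 to 0.29 and Tac1 from -1.43 to 0.19. Between layers Elavl3 ran from -0.31 to 0.15 and Elavl4 from -0.14 to 0.090. Between gastric regions Elavl3 ran from -0.56 to 0.19, Elavl4 from -0.038 to 0.41, Vip from -0.53 to 0.83, Chat from -0.090 to 0.59 and Tac1 from -0.19 to 1.62. Named genes that were called kept their direction in each alternative that gave them a value, which with genes higher in non-neuronal nuclei left out was so for 7 of 12, 24 of 37, 12 of 16 and 36 of 65.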

Other observations

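Tests chosen only after the result was seen in this part were that of free RNA in the suspension and that of depth for the immediate early genes, and the division of the 6 intestinal myenteric libraries was found by looking through the splits.

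Further genes named by the rule separated the layers. In submucosal neurons the glutamate receptor subunits Gria2 (log2 fold change 1.19, SE 0.25) and Grin3a (1.43, SE 0.25), the sodium channel gene Scn11a (1.44, SE 0.30) and the synapsin gene Syn2 (1.29, SE 0.25) were called higher than in myenteric neurons, and Syn2 was the 1 pan-neuronal gene of 14 called higher, against the neurofilament gene Nefl (-3.67, SE 0.92) lower. Clec14a (37.8 ± 14.0 against 1.59 ± 0.743 CPM), Arsi (22.9 ± 8.62 against 1.19 ± 0.768) and Adam12 (258 ± 135 against 21.9 ± 18.9) were called higher with each library left out, as was Gpc3 (44.0 ± 3.58 against 3.75 ± 0.785), which stood at 87.6 CPM in non-neuronal nuclei. The endothelin receptor Ednrb was lower, at 3.26 ± 0.780 against 17.5 ± 7.85 CPM, and the desmosomal cadherin Dsc3 at 0.732 ± 0.641 against 20.4 ± 13.8. Without submucosal small intestine replicate 1 or 2 the calls of Gria2, Grin3a, Scn11a, Syn2, Nefl and Ednrb ended (adjusted p between 0.0554 and 0.198). Those of Gria2, Grin3a, Scn11a and Syn2 also ended without submucosal colon (0.0572 to 0.175) and all of these but Grin3a without myenteric small intestine replicate 1, that of Gria2 without replicate 2, and that of Syn2 without replicate 3 (0.0503 to 0.0613). That of Nefl ended without colon replicate 1, the library labelled colon or small intestine replicates 2 or 3 (0.059 to 0.0724).

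In gastric against small intestinal neurons, Otof, which encodes otoferlin, averaged 0.227 ± 0.211 against 25.5 ± 18.1 CPM (-7.21, SE 0.75, adjusted p = 0.00108 by edgeR with Benjamini-Hochberg adjustment), Rph3a, which encodes rabphilin, 2.20 ± 0.747 against 40.3 ± 13.2, Adamts14 0.653 ± 0.335 against 25.5 ± 11.7 and Cbln2 1.05 ± 0.839 against 38.3 ± 17.7. These 4 genes stayed called with each library left out. Onecut2 (53.3 ± 20.6 against 6.30 ± 1.19 CPM) and Ptchd4 (91.1 ± 41.5 against 8.14 ± 3.69) were called higher, but whichever of the 8 libraries was left out, neither was called (adjusted p between 0.0613 and 0.253).

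Other divisions of the same libraries into groups of equal sizes test whether chance can account for a count. For the 6 libraries of colon and small intestine, the 10 splits are too few for a share under 0.05: the real counts were 16 in all neurons, 6 in inhibitory and 1 in excitatory motor-like neurons, and the highest others 843, 628 and 907. No other split called as many for stomach against small intestine (140, highest other 0 of 56 splits), stomach against colon (62, highest other 0) and the layers (1113, highest other 588 of 84 splits, not kept within organ). The same held in inhibitory neurons (50 and 316 in these organ pairs, highest other 14 in each) and in excitatory neurons (49 and 28, highest other 0 in each). The share of splits was thus under 0.05, but it was the smallest possible and was not adjusted over comparisons. Splits that mix the groups also widen the fitted spread, which can lower their counts. A structure of the libraries that goes with organ or layer is not excluded.

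The split with 843 calls points to a structure of the libraries: it sets ileum replicate 1, proximal colon replicate 1 and the library labelled colon against the other 3 intestinal myenteric libraries, with 691 genes higher and 152 lower. Depth of the summed counts as its cause is argued against by 869 calls after thinning to the smallest sum. Thinning of sums keeps the expected share of each gene, so it does not test depth per nucleus. Of the 691 genes, 689 were also higher in non-neuronal nuclei (99.7%, median log2 difference 2.19 against -0.09 for all genes), and ribosomal protein genes, 42 of 77 higher, took 0.657%, 0.842% and 0.353% of neuronal UMIs there against 0.141% to 0.212% in the 3 others. The non-neuronal pool includes the unnamed clusters of low UMI counts, which held 3591 nuclei of ileum replicate 1. Free RNA in the suspension cannot be told apart from other causes: the median ratio of smooth muscle to neuronal CPM of 5 neuropeptide genes was 1.80 in these 3 libraries and 1.02 in the 3 others, both far over the 0.1 set for nuclei without free RNA, so it was present on both sides and the test does not set them apart. No biological explanation was tested, and this division was not used to group libraries.

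The immediate early genes Nr4a3, Npas4 and Egr1 summed to 50.3 to 82.0 CPM in submucosal and 9.23 to 20.01 CPM in myenteric neurons. Depth is argued against, since 3 of these 3 genes were called after thinning. Handling or buffer acting on all nuclei cannot be told apart from an effect of the layer itself: of 6 values in glial and fibroblast nuclei of the submucosal libraries, 5 lay above each myenteric library of the organ, with 3 of 3 in glia and 2 of 3 in fibroblasts. The exception was fibroblasts of submucosal colon, at 63.28 CPM (16 UMIs) against 63.53 CPM (6 UMIs) in proximal colon replicate 1. The glial and fibroblast values of both layers rest on 2 to 21 UMIs each. A difference between the layers stays open as untested.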
